A study of Gallus gallus with 6 samples.

How the data were processed

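RNA was extracted with Trizol from primary cultures of embryonic chicken skeletal muscle cells, as proliferating myoblasts or as differentiated myotubes, and sequenced with Illumina libraries, per the labels' protocols. The series has 6 libraries, 3 of each group, and the group of each was taken from its labels. For each library the authors deposited a table with 2 measurements per gene, a raw read count and an FPKM value (fragments per kilobase of gene and per unit of library size), per the file headers. The alignment and counting tools are HISAT and HTSeq, per the submitters' processing notes, with no version. The genome build, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Coordinates are those listed in the tables, with build unknown.

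The deposited FPKM equals the read count divided by the length in the table and by the library's total count, on the FPKM scale, within 1%, for 58.6 to 59.5% of Ensembl genes with at least 50 counts. For the others it implies another length. Over all 10831 Ensembl genes with at least 50 counts in the first library of both groups, the implied length is the same in both groups in 100%. The tables also list loci without an Ensembl identifier, 1069 per myoblast table and 1710 per myotube table. For 239 of these loci with at least 50 counts in the first library of both groups, the length implied by FPKM agreed between groups in 0%. The tables list the same position and length in both groups for all 1069 shared numbers. The FPKM of these loci fits that length in 0.62 to 0.69% of cases in myoblast tables and 52.78 to 54.32% in myotube tables. Whether FPKM was computed differently in the groups, or the counts under a number belong to different loci, cannot be told from the tables, so these loci were left out of all comparisons and library sizes. They held 2.07% ± 0.06 (SD, n = 3) of counts in myoblasts and 1.70% ± 0.04 in myotubes. Each myotube table also ended in 2 rows of annotation text that name no gene and were left out, 0% of counts.

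Total counts were 16052542, 16689455 and 20981337 in myoblasts and 23519295, 22887248 and 21893152 in myotubes. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 12808 of 24881, of which 8699 carry a symbol. Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test with TMM normalization, two-sided, with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. CPM values use TMM-scaled library sizes, and intervals and floors cover counting error only. The common biological coefficient of variation was 0.0975. The comparison was fixed before the data were examined, with the count test to be used if the tables held raw counts.

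The gene lists were fixed before the data were examined, 29 lists with 904 entries, of which 710 matched a row by symbol, by an alias or, for 5, by a synonym in a RefSeq gene table of assembly GRCg7b used only for names. Lists with at least 5 tested members were tested, 28 in all, by camera from limma 3.58.1 on log2 CPM with a prior count of 1 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. Under DESeq2 and the robust fits of edgeR and limma, lists were tested by cameraPR. It is a form of camera that starts from gene statistics, here with the same preset correlation. List values of those alternatives therefore differ from the main ones in the list test as well. Genes were named by a rule fixed before the data were examined. It took 16 core genes whether called or not, the 2 called members with the largest change in each list's more frequent direction (1 for markers of other cell types and for immediate early genes), and the 5 largest rises and 5 largest falls among called genes with a symbol and separated groups. Other members of a list are named as examples chosen after their values were seen. Of 67 named genes in the tables, 5 overlap another listed gene.

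The test was run first on counts simulated from the means and library sizes of the 12808 tested genes, with a dispersion of 0.02. In them 200 genes outside the gene lists were changed between myoblasts and myotubes, and the 48 mitosis genes were set 2-fold lower. Of the 200, the test recovered 36% of genes changed 1.5-fold, 94% of those changed 2-fold, 100% of those changed 4-fold and 100% of those changed 8-fold. Of its 227 calls, the mitosis genes included, 6.2% were false. The simulated dispersion, on the scale of the squared coefficient of variation, was above that of the data. Far fewer genes were changed than were called in the data, so these shares do not measure power or error there. Alternatives were another tool (DESeq2 1.42.0), other size factors, other filters, limma on log2 FPKM with several pseudocounts and scalings, robust variance estimation, the replicate number as a block, a stricter threshold and leaving out each library.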

Results

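Gene expression was measured by RNA sequencing in cultured skeletal muscle cells of the chicken embryo. Myoblasts, the proliferating mononucleated precursors of muscle fibres, were sampled in growth medium with 15% fetal bovine serum. Myotubes, the multinucleated cells that form when myoblasts leave the cell cycle and fuse, were sampled after culture in medium with 2% horse serum. Each group had 3 libraries, all from cells at passage 1. The tables held between 16052542 and 20981337 counted reads per myoblast library and between 21893152 and 23519295 per myotube library. Of 24881 Ensembl genes in every table, between 16783 and 17188 had at least 1 read in a myoblast library and between 17909 and 17954 in a myotube library. The comparison addressed here is the one the series names, which genes differ between myoblasts and myotubes. Levels are given as CPM, counts scaled to a common library size, as mean ± SD with n = 3 per group unless stated, and fold changes as myotube relative to myoblast.

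All 48 tested mitosis genes were lower in myotubes and 27 of 42 tested sarcomere genes were higher. Camera called both lists, but neither with an estimated correlation (adjusted p = 0.1 and adjusted p = 0.15). MYF5, an early myogenic transcription factor, stood at 329 ± 20.7 CPM in myoblasts and 28.6 ± 6.54 in myotubes, 11.5-fold lower. CDK1, the kinase that drives entry into mitosis, was 9.28-fold lower. MYOM2, a protein of the sarcomere M-band, was 16.7-fold higher, from 6.66 ± 1.24 to 110 ± 14.8 CPM. PHGDH, the first enzyme of serine synthesis, rose 39.2-fold, from 52.3 ± 3.52 to 2051 ± 164 CPM. Of 12808 genes tested, 4706 were higher and 4577 lower in myotubes at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 1803 and 1417 of these changed at least 2-fold. The values of the 3 myotube libraries lay wholly above or wholly below those of the 3 myoblast libraries in 76.1% of tested genes, against 10% by chance. Labels do not say whether the libraries of a group came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical.

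Among genes with a symbol, the largest separated rises by fitted fold change were of BRN3, KCNF1, OSTN, DPT and SPON2. No read of BRN3, a POU-domain transcription factor, or of KCNF1, a potassium channel subunit, was counted in any myoblast library. Against a floor of 3 counts over the group, BRN3 was at least 88.2-fold higher and KCNF1 at least 84.0-fold higher, at 5.12 ± 1.61 and 4.91 ± 0.814 CPM in myotubes. OSTN, a secreted peptide made by bone and muscle, rose 92.1-fold to 22.1 ± 3.15 CPM, or 149-fold without myoblast replicate 2, from 12 counts over the myoblast libraries. DPT, a protein of the extracellular matrix, rose 89.3-fold to 66.3 ± 2.91 CPM, and the secreted matrix protein gene SPON2 rose 80-fold to 139 ± 23.0 CPM. The largest separated falls by fitted fold change were of S100A8, CSF3, SOX10, TSPAN8 and TPPP3. S100A8 had 110 counts over the myoblast libraries and 0 over the myotube libraries, at least 48.8-fold lower. Its place among these genes rests on a fitted 342-fold change against 0 counts. SOX10, a transcription factor of the neural crest and its derivatives, fell from 16.6 ± 0.627 to 0.131 ± 0.0859 CPM, 121-fold. CSF3, a granulocyte growth factor, fell 132-fold from 12.4 ± 0.379 CPM. Its listed position overlaps that of THRA on the same strand, so its counts are uncertain. TPPP3, a tubulin-binding protein gene, fell 69.3-fold from 27.7 ± 3.62 CPM. TSPAN8, a tetraspanin gene, had 165 counts in myoblasts and 2 in myotubes, a ratio of 0.00912 (95% exact interval 0.00109 to 0.0335, which covers counting error only).

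**Figure D1:**
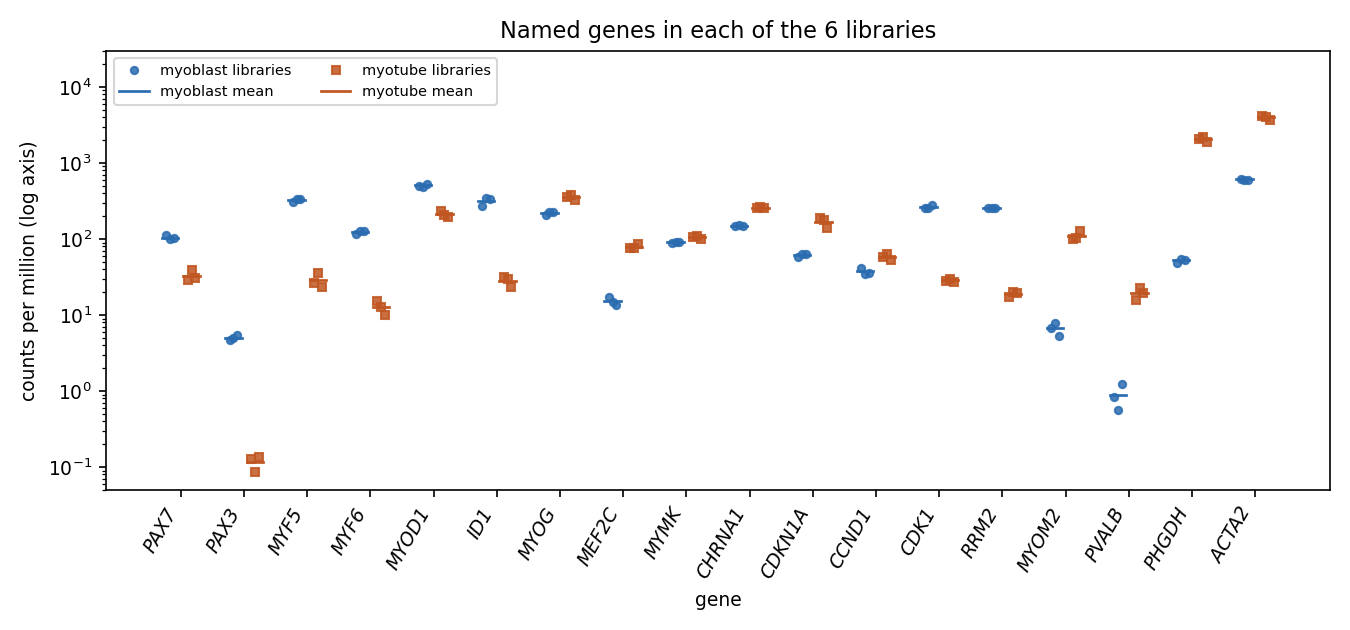
CPM (vertical axis, logarithmic) of 18 named genes (horizontal axis) in each of the 3 myoblast libraries (circles) and 3 myotube libraries (squares), with the group mean as a line. MYF5 went from a mean of 329 to 28.6 CPM and PHGDH from 52.3 to 2051 CPM, and the libraries of the 2 groups do not overlap for any gene drawn.

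The muscle-determining transcription factors moved in opposite directions. MYF5 and MYF6, which lie side by side on chromosome 1 (MYF5 at 40002758 to 40003972, MYF6 at 39998073 to 39999566), fell 11.5-fold and 9.75-fold, and MYF6 went from 124 ± 5.59 to 12.7 ± 2.51 CPM. MYOD1, which commits cells to the muscle lineage, fell 2.39-fold from 507 ± 21.9 to 212 ± 18.8 CPM (chromosome 5, 12184436 to 12187655). MYOG, the factor that drives terminal differentiation, rose 1.62-fold from 219 ± 12.3 to 355 ± 31.4 CPM (chromosome 26, 968610 to 972124; edgeR adjusted p = 1.4e-05). Its partner MEF2C rose 5.22-fold to 79.1 ± 5.02 CPM, and the cofactor EYA4 rose 3.08-fold to 36.0 ± 4.03 CPM. Of the 12 myogenic regulators tested, 8 rose and 4 fell. As a set they were not called by camera (adjusted p = 0.46), with a median log2 fold change of 0.66 and a mean of -0.02. PAX7, the marker of muscle stem cells, fell 3.18-fold from 104 ± 6.51 to 32.8 ± 5.15 CPM. It spans other listed genes on the opposite strand, and whether counting used strand is not given in the sources used here. PAX3, its paralog in muscle progenitors, fell 41.0-fold from 5.03 ± 0.459 to 0.117 ± 0.0267 CPM. Of the 16 progenitor and Notch genes tested, 4 rose and 8 fell (camera adjusted p = 0.34), and NOTCH1 was among those that rose, from 89.2 to 209 CPM.

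Genes of BMP and TGF-beta signalling and the ID genes were lower in myotubes. ID1, ID2 and ID4 encode inhibitors of the MYOD family, and ID1 fell 11.2-fold from 316 ± 36.7 to 28.2 ± 4.24 CPM (chromosome 20, 10207842 to 10209004). ID4 fell from 1111 to 155 CPM and ID2 from 248 to 39.2 CPM. GREM1, a BMP antagonist, fell 10.6-fold from 3.63 ± 0.985 CPM. The abundant TGF-beta target TGFBI fell from 2763 to 483 CPM. Of 21 tested members, 14 fell, 5 rose and 2 were not called. The median log2 fold change was -1.32 and the camera adjusted p was 0.0029, or adjusted p = 0.23 with an estimated correlation.

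Cell division genes fell almost without exception. All 48 tested mitosis genes fell, 46 of them at least 2-fold. UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell 13.4-fold from 147 ± 9.45 to 11.0 ± 1.51 CPM, and CDK1 fell from 265 ± 16.3 to 28.6 ± 1.54 CPM. Of the 41 tested DNA replication genes, 40 fell and 1 was not called. RRM2, a subunit of ribonucleotide reductase, fell 13.4-fold from 256 ± 2.57 to 19.0 ± 1.47 CPM, and thymidine kinase TK1 fell 10.8-fold to 18.5 ± 1.52 CPM. The medians on the log2 scale were -2.39 for mitosis (camera adjusted p = 2.8e-21) and -1.98 for DNA replication (camera adjusted p = 3.4e-15). With an estimated correlation neither list was called, at adjusted p = 0.1 for mitosis and adjusted p = 0.15 for DNA replication. Regulators of cell cycle exit were mixed, with 11 higher and 9 lower of 21. CDKN1A, which encodes the inhibitor p21, rose 2.76-fold from 61.3 ± 3.58 to 169 ± 24.2 CPM, and cyclin genes CCND2 and CCNG1 rose 3.40-fold and 3.05-fold. CCND1, the cyclin that promotes entry into S phase, rose 1.55-fold from 37.6 ± 3.57 to 58.2 ± 4.75 CPM, while CCND3 went from 106 to 54.9 CPM and CDK2 from 78.6 to 23.1 CPM. That list was not called (camera adjusted p = 0.8), and its median of 0.32 (0.20 by quantile normalization) and mean of -0.01 differed in sign.

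Contractile genes were higher as a group, with exceptions. Of the 42 sarcomere genes tested, 27 rose, 8 fell and 7 were not called, and 20 rose at least 2-fold. MYBPC1, a slow-muscle myosin-binding protein, rose 57.2-fold from 0.455 ± 0.114 to 26.0 ± 5.27 CPM, next to MYOM2. Fast troponin T (TNNT3) rose from 72.8 to 388 CPM, myosin light chain MYL1 from 148 to 376 CPM and ACTN2 from 70.02 to 259 CPM. CSRP3 fell from 25.1 to 5.61 CPM, MYL4 from 21.1 to 4.95 CPM and TPM1 from 2995 to 2186 CPM. The median log2 fold change was 0.83 and the camera adjusted p was 0.00025, or adjusted p = 0.15 with an estimated correlation. Of 71 listed sarcomere genes, 46 matched a row. These took 0.685% ± 0.00676 of summed FPKM in myoblasts and 0.870% ± 0.0161 in myotubes (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The share leaves out the unmatched genes. MYH7B, a slow myosin heavy chain, had 40 counts over the myoblast and 162 over the myotube libraries and lay under the filter. The names CKM, ACTA1, TNNT2 and MKI67 were not matched to a row, and these genes were not analysed here.

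Genes of calcium release and uptake rose in 11 of 16 cases and fell in none. PVALB, the calcium buffer of fast fibres, rose 21.2-fold from 0.884 ± 0.350 to 19.4 ± 3.51 CPM, and the triad protein TRDN rose 5.02-fold to 11.0 ± 2.47 CPM. The camera adjusted p was 0.0067, or adjusted p = 0.17 with an estimated correlation. Of 12 genes of the acetylcholine receptor and endplate, 9 rose and 3 fell, but the set missed the threshold (camera adjusted p = 0.065, or adjusted p = 0.048 without myotube replicate 1 and 0.022 with no filter). CHRNA1, the receptor's alpha subunit, rose 1.71-fold from 150 ± 1.94 to 256 ± 5.15 CPM (chromosome 7, 16865856 to 16875595), CHRND rose 3.42-fold and ERBB3 rose 3.92-fold. AGRN, which encodes agrin, fell from 59.8 to 20 CPM. Fusion genes gave no list call: of 21, 7 rose and 7 fell (camera adjusted p = 0.97), against 9 and 4 on the TPM scale and 11 and 6 by quantile normalization. MYMK, the membrane activator of fusion listed under its older name TMEM8C, rose 1.16-fold from 90.7 ± 2.61 to 106 ± 5.61 CPM (edgeR adjusted p = 0.0076). DYSF, a membrane repair protein gene, rose 3.52-fold, and the integrin gene ITGA4 rose 2.03-fold. In the dystrophin complex and muscle membrane list, 6 rose and 6 fell of 17, or 7 and 4 on the TPM scale (camera adjusted p = 0.97), with ITGA7 up 3.44-fold. Its median of -0.06 and mean of 0.22 differed in sign.

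Nuclear genes of oxidative phosphorylation were slightly lower in myotubes. Of 41 tested, 39 fell, but 2 of these by 2-fold or more, and the median log2 fold change was -0.50. By quantile normalization 23 fell and 1 rose, with a median of -0.20, and on the TPM scale 34 fell, with a median of -0.31. Cytochrome c (CYCS) fell 2.5-fold from 367 ± 2.72 to 147 ± 3.73 CPM, and ATP5MC3, a subunit of the ATP synthase ring listed as ATP5G3, fell 2.19-fold to 180 ± 4.46 CPM. The camera adjusted p was 2.2e-09, or adjusted p = 0.42 with an estimated correlation. Random lists of 41 genes of like length and level had a median of -0.40, and 19.1% of 10000 such lists lay as low. Mitochondrial genome rows held 3.26% ± 0.20 of counts in myoblasts and 3.55% ± 0.62 in myotubes. Genes of fatty acid oxidation split into 7 higher and 8 lower of 21 (camera adjusted p = 0.97), and the larger side turned with scaling, at 11 and 6 on the TPM scale, 10 and 7 with library totals and 5 and 9 with median-of-ratios scaling. LPL was 3.17-fold and ACAA2 1.70-fold lower in myotubes. This list's median of 0.06 was positive while camera placed it lower. Of 17 glycolysis and creatine genes, 7 rose and 5 fell, or 10 and 4 on the TPM scale and 9 and 3 by quantile normalization (camera adjusted p = 0.69). AMPD1, the muscle AMP deaminase, rose 6-fold to 9.55 ± 0.524 CPM, GATM, which makes the creatine precursor, rose 5.13-fold, and muscle enolase ENO3 went from 28.6 to 73.0 CPM.

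Cholesterol synthesis genes were lower, with 21 of 25 called lower and 3 higher. INSIG1, a sterol-responsive regulator of this pathway, fell 5.21-fold from 297 ± 14.9 to 57.0 ± 4.17 CPM, and lanosterol synthase LSS fell 4.24-fold to 50.4 ± 1.65 CPM. The members that rose were INSIG2, FASN and ACACA, of which FASN and ACACA make fatty acids. The median log2 fold change was -1.33 and the camera adjusted p was 4e-06, or adjusted p = 0.1 with an estimated correlation. Ribosomal protein genes showed 8 higher, 19 lower and 33 not called of 60 (camera adjusted p = 0.31). RPL38 fell 2.05-fold and RPS21 fell 1.72-fold, although ribosomal protein genes have near-identical copies that can share reads. The split of this list turned on the scaling: with each library rescaled to the TPM scale, 26 were higher and 6 lower, and by quantile normalization 19 were higher and 15 lower. Of 29 ribosome biogenesis genes, 8 rose and 13 fell (camera adjusted p = 0.34), but 11 rose and 10 fell on the TPM scale and 11 and 9 by quantile normalization, with NHP2 2.09-fold and NOP16 1.91-fold lower.

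Extracellular matrix genes changed widely in both directions. Of 41, 24 rose and 13 fell, and the call of the list as higher turned on the setting. The camera adjusted p was 0.058, but it was 0.038 and 0.04 without myoblast replicates 1 and 2, and 0.043, 0.042 and 0.046 without myotube replicates 1, 2 and 3. Without myoblast replicate 3 it was 0.082, and 6 of 15 other alternatives called the list, over a range of adjusted p from 6.5e-05 to 0.76. The lowest values came from cameraPR, at adjusted p = 6.5e-05 with DESeq2 and 0.00044 and 0.0005 with the robust fits of edgeR and limma. In the same libraries 12 of 15 fibroblast markers rose. OGN rose 13.6-fold from 1.71 ± 1.03 to 23.9 ± 9.54 CPM and FBLN1 rose 13.1-fold from 35.6 ± 4.66 to 467 ± 39.7 CPM. OGN overlaps CENPP on the opposite strand. COL1A2 went from 2179 to 6469 CPM and MMP2 from 638 to 3728 CPM, while THBS1 fell from 5954 to 762 CPM and POSTN from 964 to 174 CPM. Of 23 genes of IGF and myostatin signalling, 14 rose and 6 fell (camera adjusted p = 0.19). MSTN, the inhibitor of muscle growth, rose 3.31-fold from 4.38 ± 0.964 to 14.4 ± 0.154 CPM, and DDIT4, an inhibitor of mTORC1, rose 4.98-fold to 548 ± 109 CPM. IGFBP4 fell from 1324 to 242 CPM and IGFBP2 from 403 to 48.4 CPM.

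Genes of the unfolded protein response were called higher in 14 cases and lower in 9 of 23, without a call for the list (camera adjusted p = 0.29). Of 15 alternatives, 4 called it higher, over a range of adjusted p from 0.00085 to 0.68. By cameraPR these were DESeq2 (adjusted p = 0.00099) and the robust fits of edgeR (0.005) and limma (0.00085). By camera it was quantile normalization (adjusted p = 0.0096). The largest rises, PHGDH and CHAC1, with CHAC1 up 9.48-fold to 357 ± 75.5 CPM, belong to the amino acid branch. HYOU1 went from 364 to 234 CPM and MANF from 316 to 153 CPM. Of 17 interferon response genes, 5 rose and 6 fell, or 6 and 5 on the TPM scale (camera adjusted p = 0.8), with OASL 5.13-fold lower (7.92-fold without myotube replicate 1) and IRF7 2.46-fold lower. Of 15 immediate early genes, kept as a mark of handling and serum response, 3 rose and 8 fell (camera adjusted p = 0.13). The camera adjusted p was 0.048 without myotube replicate 1 and 0.031 with no filter, and the cameraPR adjusted p was 0.044 with DESeq2. NR4A3 fell 7-fold to 3.66 ± 0.593 CPM and FOS went from 74.0 to 13.7 CPM.

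Markers of other cell types moved apart. Blood cell and macrophage markers fell in 11 of 13 cases and rose in none. C1QB, a complement component of macrophages, fell 8.97-fold from 234 ± 5.50 to 26.1 ± 3.14 CPM. The median log2 fold change was -1.28 and the camera adjusted p was 2.3e-05, or adjusted p = 0.17 with an estimated correlation. Fibroblast markers rose in 12 of 15 cases, with a median of 1.45 (camera adjusted p = 0.004, or adjusted p = 0.27 with an estimated correlation). DPT rose most, PDGFRA went from 16.04 to 96.7 CPM, TWIST1 and MFAP5 fell, and THY1 stood at 942 and 896 CPM. Smooth muscle and myofibroblast markers were mixed, with 6 higher and 5 lower of 12 (camera adjusted p = 0.8). Smooth muscle actin ACTA2 rose 6.51-fold from 610 ± 6.78 to 3972 ± 248 CPM, and its reads may be shared with other actin genes of nearly the same coding sequence. Cartilage and tendon markers gave 5 higher and 4 lower of 10 (camera adjusted p = 0.69), with CILP 6.30-fold higher. Adipocyte markers gave 3 higher and 4 lower of 9, or 4 and 3 on the TPM scale (camera adjusted p = 0.97), with ADIPOQ 15.5-fold lower. Neural and Schwann cell markers gave 2 higher and 2 lower of 5 (camera adjusted p = 0.97), with SOX10 lower and NEFL 6.01-fold higher. Too few endothelial markers were tested for a list test, and LYVE1 among them rose 8.39-fold from 1.17 ± 0.0589 to 9.84 ± 1.92 CPM.

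**Figure D2:**
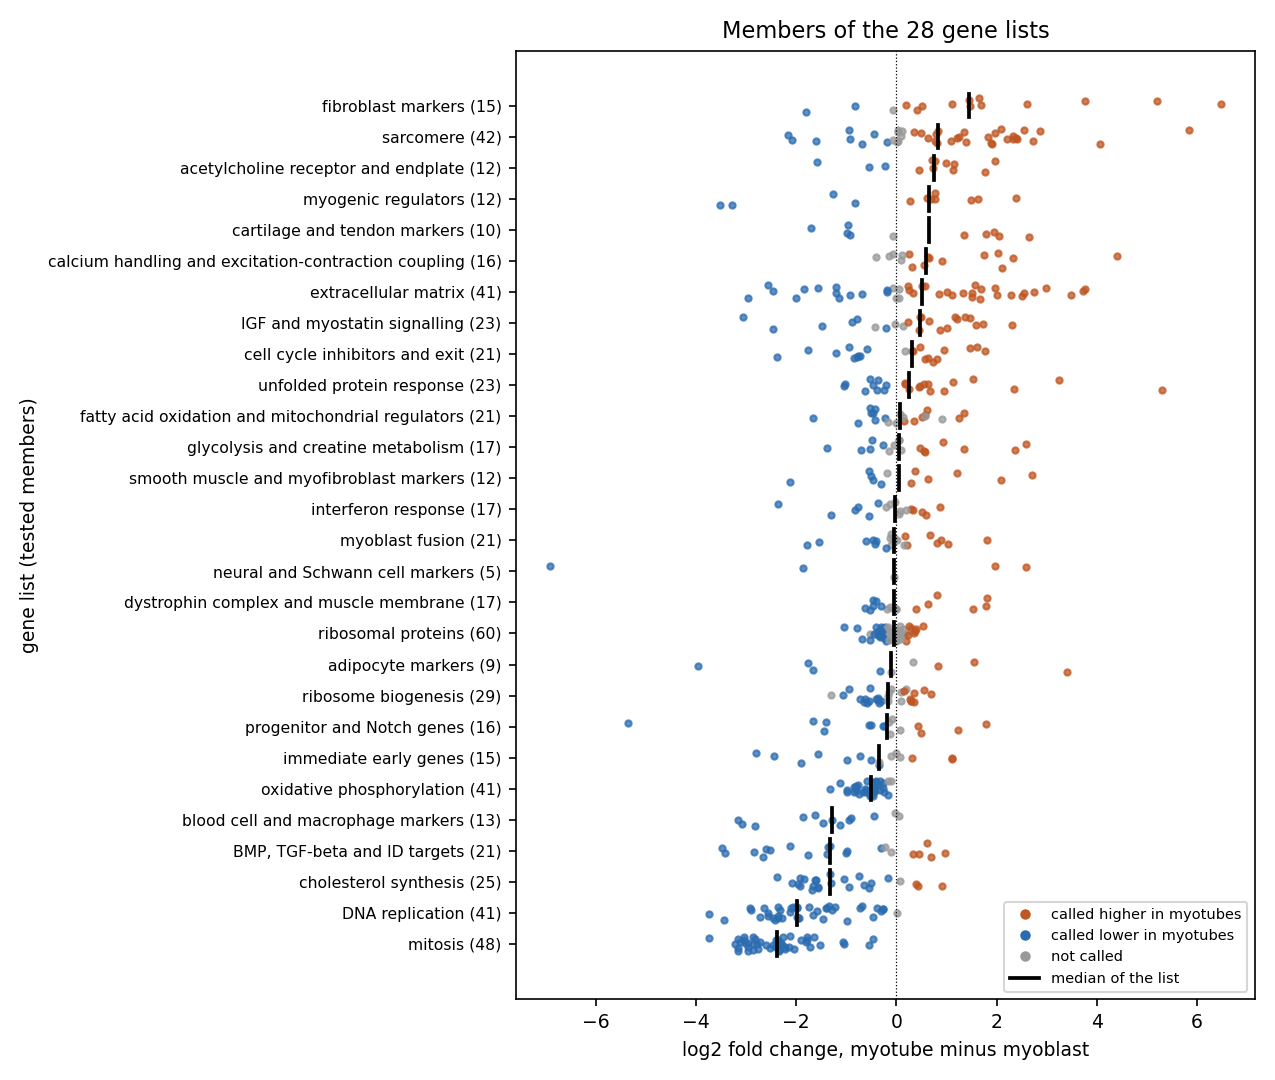
Log2 fold change of each tested member (horizontal axis, myotube minus myoblast) of the 28 gene lists (vertical axis, with the number of tested members). Points are members called higher, called lower or not called at an adjusted p under 0.05, and black lines are medians. The medians run from -2.39 for mitosis to 1.45 for fibroblast markers.

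Camera called 9 of the 28 lists, 3 higher and 6 lower, and called 0 with an estimated correlation between genes. The estimated correlation was -0.0241 for cholesterol synthesis and 0.0074 for calcium handling, neither above the preset 0.01. A larger correlation therefore does not account for the loss of the call in these lists. The preset and estimated settings must differ in more than the correlation, and the cause was not tested. A call lost with an estimated correlation thus does not by itself show that correlation between genes undid it. Fry asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. By fry, mitosis had an adjusted p of 2.1e-06 and sarcomere 7.2e-06. Most lists had a fry adjusted p under 0.05, among them lists that camera did not call. These included the unfolded protein response (5.3e-05), extracellular matrix (0.00077) and myogenic regulators (0.0056). Others did not pass, such as myoblast fusion (0.62), so fry does not single out mitosis and sarcomere. Adjusted over the list alone, the counts of called members were those given for each list, except that 41 oxidative phosphorylation genes fell and that 7 ribosomal protein genes rose. The first principal component held 88.1% of the variance and separated the groups. Spearman correlations were between 0.991 and 0.995 within groups and between 0.883 and 0.906 across them, over genes, which are not independent replicates. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was between 6.39 and 20.5 within groups. The 20 highest genes held 12.8% ± 0.226 of summed FPKM in myoblasts and 12.4% ± 0.452 in myotubes, a difference within the spread (exact permutation p = 0.3, two-sided). Of the 21 fixed main lists, no share of summed FPKM could fall under an exact p of 0.1 by design, and after Benjamini-Hochberg adjustment over 23 shares the smallest was 0.121.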

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

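The tables hold a signal that the comparisons do not use. The myotube tables carry 641 numbers of loci without an Ensembl identifier that the myoblast tables do not carry, and 547 of them had more than 3 counts in every myotube library. Their counts summed to between 187854 and 215697 per myotube library. The myoblast tables have no row under these numbers, so no difference between groups can be read from them. The 6 tested Ensembl genes that overlap any locus without an Ensembl identifier, in the tables of either group, had a median log2 fold change of 0.48, against 0.01 for the others, and 5 of the 6 were called higher.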

How the results depend on the processing

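Over alternatives other than leaving out a library, genes higher ranged from 3711 to 5865 and genes lower from 3492 to 5001. With each library left out in turn they ranged from 4338 to 4619 and from 4249 to 4539. Restricting the test to the 9764 genes with a mean FPKM of at least 5 left 1128 genes at least 2-fold higher and 879 at least 2-fold lower. With camera's correlation estimated, 0 lists were called; the other alternatives called between 9 and 12. Of 586 values of single lists, 20 gained a call, and the 9 that lost one did so under the estimated correlation. The share of summed FPKM held by the highest genes changed sign from -0.38 percentage points for 20 genes to 0.828 for 100 genes; the cause was not tested, and neither difference could pass its test by design. On the TPM scale, 62.7% of calls were higher, against 50.7%, and the median log2 fold change of all genes was 0.19. Quantile normalization called 23 genes in the opposite direction. All 1301 values of named genes kept direction and call. Apart from the core genes, these genes were named because they were called with large changes in the same data. Their stability is therefore largely built in and says little about other genes. With the replicate number as a block, 4447 genes were higher and 4337 lower and 9 lists were called, and the libraries with the same number correlated at -0.04, 0.10 and -0.15, so not every library correlated best with its own number. Total-count scaling without TMM, the robust limma fit and leaving out genes that overlap loci without an Ensembl identifier were chosen after seeing the data. DESeq2 gave no adjusted p for 9 genes. In simulation at these library sizes, with a dispersion of 0.02 and few genes changed, 36% of 1.5-fold changes were recovered. In the data the dispersion was smaller and 72.5% of tested genes were called, so this share does not measure the power of the comparison.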

Other observations

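The gene lists in this paragraph and the next were written after the data were seen, so their tests describe these libraries and are not independent evidence. Genes of serine synthesis and one-carbon metabolism were mostly higher in myotubes. Of 16 tested, 11 rose and 4 fell (camera adjusted p = 0.0031, or adjusted p = 0.072 with an estimated correlation). After PHGDH, PSPH rose 5.43-fold from 17.6 ± 0.367 to 95.5 ± 6.19 CPM and PSAT1 rose 5.07-fold, which completes the 3 steps from glycolysis to serine. ALDH1L2, a mitochondrial folate enzyme, rose 27.1-fold from 6.75 ± 0.807 to 182 ± 2.14 CPM. Those that fell were TYMS, which makes thymidylate for DNA synthesis, 4.38-fold lower, the cytosolic SHMT1, 2.37-fold, GCSH of the mitochondrial glycine cleavage system, 1.69-fold, and MTHFD1, 1.19-fold. Genes induced by amino acid shortage rose in 17 of 23 cases and fell in 3 (camera adjusted p = 4e-05, or adjusted p = 0.15 with an estimated correlation). SLC7A11, the cystine carrier, rose 14.8-fold and the neutral amino acid carrier SLC7A5 rose 9.86-fold from 65.6 ± 5.49 to 646 ± 41.3 CPM. The factor that drives many of these genes, ATF4, rose 1.46-fold. Of the members of these lists, 3 and 4 also belong to lists fixed before the data were examined.

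Lysosomal genes were lower in myotubes, with 23 of 29 lower and 4 higher (camera adjusted p = 3.7e-05, or adjusted p = 0.072 with an estimated correlation). The cholesterol transfer protein gene NPC2 fell 4.82-fold from 556 ± 30.2 to 115 ± 2.90 CPM, the protease genes CTSK and CTSC fell 3.30-fold and 2.99-fold, and ATP6V0D2, a proton pump subunit of phagocytes and osteoclasts, fell 10.3-fold. GALC and LAMP2 were among those that rose. Macrophage markers fell in the same libraries, in 11 of 13 cases, so the fall of lysosomal genes cannot be assigned to muscle cells. The median of the lysosomal list was -0.76, or -0.48 by quantile normalization. HOX genes, which set position along the body and limb, rose in 11 of 16 cases and fell in 3 (camera adjusted p = 0.0095, or adjusted p = 0.18 with an estimated correlation). HOXC8 rose 23.8-fold to 7.46 ± 0.366 CPM, HOXC10 rose 2.45-fold to 26.3 ± 3.99 CPM, and HOXA13 fell 1.99-fold. Since 12 of 15 fibroblast markers rose in the same libraries, the rise of HOX genes cannot be assigned to muscle cells. Melanocyte and neural crest genes fell in 6 of 8 cases and rose in 2 (camera adjusted p = 0.029, or adjusted p = 0.15 with an estimated correlation). MLANA, a melanosome protein gene, fell 35.2-fold from 119 ± 7.95 to 3.36 ± 0.575 CPM, next to SOX10, while ERBB3 rose. Of the lysosomal and melanocyte members, 1 and 3 also belong to fixed lists.

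In the 3 patterns weighed next, the tests of mitochondrial genome genes, of cells from female embryos, of the share of muscle cells and of the share of fibroblasts were chosen after the results were seen. Oxidative phosphorylation genes were lower by a median of 0.50 on the log2 scale in myotubes, or of 0.20 by quantile normalization, with 23 lower and 1 higher of 41. Less mitochondrial RNA of every kind is argued against: 14 genes of the mitochondrial genome had a median log2 fold change of 0.0732, with a lower quartile of -0.18. Lower counting of short transcripts in the myotube libraries may account for the fall, since 19.1% of 10000 random lists of like length and level had a median as low. The median length in the list was 933 bases, against 1830 for other tested genes, and fold change rose with length (Spearman rho 0.16 over genes, which are not independent replicates). None of 10000 matched lists reached the medians of mitosis, DNA replication, cholesterol synthesis, BMP and TGF-beta targets, macrophage markers, fibroblast markers or sarcomere, and 3.24% reached that of calcium handling.

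Genes on the W chromosome, which in birds females alone carry, were higher in myotubes. Of 19 tested, 18 had a positive log2 fold change, 15 were called higher and 0 lower, and the median log2 fold change was 1.27, with quartiles of 0.87 and 1.59. W rows held 164 ± 7.98 CPM in myoblasts and 411 ± 13 in myotubes (SD, n = 3), and the W copy of HNRNPK went from 72.8 to 175 CPM. A larger share of cells from female embryos in the myotube cultures may account for this: the Z median minus the autosome median was -0.0837 (log2), as low as in 1.4% of 10000 random gene sets, but 6 of 29 autosomes with at least 20 tested genes had a median below that of Z, down to -0.304 on chromosome 25, so this stays open. A different share of female cells would mean a different mix of embryos in the groups, which every comparison here would carry. A switch from Z to W copies with differentiation stays open as well, since only 1 Z gene shares a name with a tested W gene.

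Markers of other cell types differed between the cultures, and no sort is named in the labels. A lower share of muscle cells in the myotube cultures, with the other types kept in proportion, would raise markers of every other type. Blood cell and macrophage markers had a median of -1.28 (upper quartile -0.90), which argues against that as the whole account. A lower share of muscle cells with a changed mix of the other types stays open, because these values cannot decide it. A larger share of fibroblasts may contribute to the rise of fibroblast and matrix genes, but 2 of 15 fibroblast markers were called lower, and the most abundant ones moved unevenly, COL3A1 from 1790 to 2555 CPM, THY1 from 942 to 896 CPM and DCN from 638 to 1369 CPM. A change within the fibroblasts or in muscle cells themselves cannot be told apart from it, because 4 of the 15 markers also belong to the matrix list and no cell type was measured alone. Differentiation itself, the difference the design names, stays open as a biological account and was not tested. All myoblast libraries came from medium with 15% fetal bovine serum and all myotube libraries from medium with 2% horse serum. The amount and kind of serum therefore cannot be told apart from differentiation in any comparison here.

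The real split of the libraries called 9283 genes, and the highest of the other 9 splits called 8, so 1 of 10 splits gave as many. It called 9 lists, and 5 of 10 splits called at least 9, with 10 the highest of the others. With 10 splits no share can fall under 0.05. Every other split also puts libraries of both groups on each side, in unequal numbers. Part of the group difference therefore stays between the sides and part adds to the spread within them. These splits do not show what chance alone would give, and no conclusion is drawn from them. An unnamed row of the mitochondrial genome, 976 bases long, stood at 586, 21.2 and 616 CPM in the myoblast libraries and at 638, 10.6 and 13.1 CPM in the myotube libraries. Another unnamed row, 1621 bases long, stood at 412.5, 176.2 and 563.9 CPM in the myoblast libraries and at 1719, 679.2 and 846.9 CPM in the myotube libraries. Both rows are among the 14 mitochondrial genome genes whose median is given above.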
